A study of Homo sapiens with 44 samples.

How the data were processed

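OVCAR5 cells, labeled as ovarian carcinoma cells that carry a reporter of IFNγ sensing and CFP, were grown in culture and stimulated continuously for 2, 6, 12 or 24 h. Total RNA with an integrity number above 8 went into stranded mRNA libraries that were sequenced on an Illumina HiSeq instrument in multiplexed pools. There were 44 libraries: 11 treatments at 4 durations, with 1 library for each treatment and duration. The sample numbers of the 2 h and 6 h libraries run apart from those of the 12 h and 24 h libraries, which points to a pair of sequencing pools aligned with duration. The source and purity of the cytokines and the donor of the T cells in the co-culture are not given in the sources used here.

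Each deposited table gave, per gene, the expected counts estimated by Salmon, TPM computed by the authors, and the gene length and effective length. The submitters' processing notes also name FastQC, UMI-tools, Trim Galore, STAR, SAMtools, Picard, StringTie, bedtools, DESeq2 and Cell Ranger with the GRCh38 genome. Their versions and roles are not given in the sources used here, nor is the strand that was counted. Expected counts were rounded to whole numbers before testing, and between 18.58% and 20.57% of genes per library had a fractional value before rounding. TPM and lengths were read but not tested. Of 33538 gene identifiers, 33113 were named from a gene name table, 343 from the GENCODE v29 annotation, and 82 kept no name. Coordinates are those of v29 on GRCh38.

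Total estimated counts per library ran from 9586125 to 16270128. The range was 10198003 to 13140065 at 2 h, 10757588 to 16270128 at 6 h, 10139796 to 15179475 at 12 h and 9586125 to 11952129 at 24 h, so that depth does not follow duration strongly. Mitochondrially encoded transcripts took 7.12% to 9.81% of counts and the 10 most abundant genes 7.85% to 10.1%. Correlations of log2 CPM between libraries ran from 0.896 to 0.990, and for all 44 libraries the most similar library was of the same duration. No pair of libraries was as close as the same library sequenced again would be. Among the 20 closest pairs the lowest ratio of chi-square to degrees of freedom was 1.51, above that of sampling error alone. Separate libraries made from the same culture are not excluded by this.

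Counts were analyzed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by the filterByExpr function (minimum count 10, minimum total 15), which left 14469 genes. Library sizes were scaled by TMM (factors 0.896 to 1.081). All 44 libraries were fitted together with a factor for duration, a factor for treatment, and for each treatment a slope on the centered log2 of duration, which gave 24 coefficients and left 20 residual degrees of freedom. Treatment effects are thus fitted values at the mean log2 duration, weighted by counts, and not plain means of the 4 log2 ratios. Slopes are changes of the treatment effect per doubling of duration. Genes were tested by the robust quasi-likelihood F test of edgeR with Benjamini-Hochberg adjustment, and those under an adjusted p of 0.05 were called. The median biological coefficient of variation was 8.4%. The SE of a log2 fold change was derived from its F statistic. With 1 library per treatment and duration, the variation between libraries of the same condition was not measured directly and comes from the spread around the fitted slopes.

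The comparisons were each treatment with unstimulated cells, IFNγ 100 ng/ml with TNFα 10 ng/ml, IFNγ 100 with 1 ng/ml, TNFα 10 with 1 ng/ml, supernatant 1/2 with the combination, the interaction of the cytokines on the log2 scale, and the slopes of IFNγ 100 ng/ml, TNFα 10 ng/ml and supernatant 1/2. The groups, these comparisons, the rule for naming genes, the gene lists and the alternatives were chosen before the data were examined. Differences of slopes between doses and the comparison of supernatant 1/200 with IFNγ 1 ng/ml were added later. Genes named outside the lists are those with the largest changes in either direction that passed the test and had a mean log2 CPM of at least 0. Except for slopes, they also had to change with the same sign at each of the 4 durations. Where unstimulated cells had 1 to 3 counts in all, the ratio of pooled counts is given with a 95% exact binomial interval; where they had none, a floor is given that assumes 3 counts. Both cover counting error only. Time courses are given as CPM, the estimated counts of a gene scaled to the size of its library, of single libraries. Log2 ratios of single durations were taken from log2 CPM with a prior count of 2, which pulls ratios of low counts towards 0.

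The analysis used 27 fixed gene lists: class I and class II antigen presentation, JAK-STAT and interferon factors, guanylate-binding proteins, CXCR3 ligands, antiviral genes, checkpoint ligands, tryptophan catabolism, NF-κB feedback and subunits, inflammatory chemokines and cytokines, leukocyte adhesion, complement, cell death, cell cycle, immediate-early genes, hypoxia and glycolysis, ATF4 and ER stress, cholesterol synthesis, acute phase, TGF-β response, matrix proteases, oxidative stress, epithelial identity, mitochondrially encoded transcripts, and markers of T cells, fibroblasts and myeloid cells. Members past the test are counted over all genes, and again after adjustment over the list alone where that differs. The camera test of limma was run on 26 lists with its preset correlation of 0.01 and with a correlation estimated per list. It covered the 4 comparisons of IFNγ 100 ng/ml, TNFα 10 ng/ml, supernatant 1/2 and the combination with unstimulated cells. Its p-values were adjusted over these 104 tests together. The fibroblast list had 1 measured member (COL1A1: 0.06 ± 0.27 with IFNγ 100 ng/ml, -0.49 ± 0.28 with TNFα 10 ng/ml, 0.14 ± 0.27 with the combination).

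The fit was tested on simulated counts drawn around the mean of each gene in these libraries, with 200 genes changed among 14146 (14163 for slopes). Simulated effects were constant over duration, or linear in its log2 for slopes, so that the fitted model held by construction. The shares below do not cover effects that curve with duration. IDO1 with IFNγ 100 ng/ml, for example, had log2 ratios of 3.95, 11.94, 10.6 and 11.17 at 2, 6, 12 and 24 h. For IFNγ 100 ng/ml against unstimulated cells 80.3% of changes of 1.52-fold, 97.1% of 2-fold and 100% of 4-fold were found, and 4.6% of calls were false. For the interaction the shares were 67.2%, 89.9% and 94.3% with 6.1% false. For slopes 50.7% of 1.23-fold, 89.1% of 1.52-fold and 97% of 2-fold changes per doubling were found with 1.9% false.

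Alternatives were scaling by RLE, no filter on low counts, no slope terms, DESeq2 1.42.0 with the same design, only the 8 libraries of a comparison, only 2 h and 6 h, only 12 h and 24 h, and leaving out each library in turn. The fits on only the 8 libraries, only 2 h and 6 h or only 12 h and 24 h also had no slope terms. Their counts therefore mix the use of fewer libraries with changes over time that stay in the spread. Each comparison was also repeated for other splits of its libraries into groups of the same sizes. Some genes that share reads with a near-identical or overlapping gene (C4A and C4B, BLOC1S5-TXNDC5, RASA4B, GTF2IRD2B, TPSB2 and OR2I1P among them) were left out of the text, and sex-linked genes were not reported. Results on some other single genes are not reported here.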

Results

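To compare how tumor cells answer cytokines that T cells release, messenger RNA was sequenced from OVCAR5 cells, labeled as ovarian carcinoma cells. They carried a reporter of IFNγ sensing. The cells received IFNγ (0.01, 1 or 100 ng/ml), TNFα (0.1, 1 or 10 ng/ml), IFNγ 100 ng/ml plus TNFα 10 ng/ml, or supernatant of a tumor-cell and T-cell co-culture diluted 1/2, 1/200 or 1/20000. With unstimulated cells this made 11 treatments, each at 2, 6, 12 and 24 h of continuous exposure, with 1 library per treatment and duration. Unless stated otherwise, each value is a fitted log2 fold change ± SE, with 4 libraries against the 4 unstimulated ones (n = 4). It is the effect at the mean log2 duration, weighted by counts, and can exceed the log2 ratios of the single durations. For STEAP4, IFNγ 100 against TNFα 10 ng/ml gave 7.28, with log2 ratios of 2.94, 5.46, 5.27 and 4.65 at 2, 6, 12 and 24 h. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All p-values measure only the spread between these libraries, which are not stated to be separate cultures.

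The number of changed genes grew with dose for each stimulus. IFNγ changed 6, 1089 and 2293 genes at 0.01, 1 and 100 ng/ml, and TNFα changed 813, 2734 and 3535 at 0.1, 1 and 10 ng/ml, of 14469 tested genes. Supernatant changed 1 gene at 1/20000, 1569 at 1/200 and 6281 at 1/2, and the combination changed 6644. Genes that rose outnumbered those that fell under each cytokine alone (1357 and 936 for IFNγ 100 ng/ml, 2073 and 1462 for TNFα 10 ng/ml). The split was nearly even for supernatant 1/2 (3267 rose, 3014 fell) and for the combination (3405 rose, 3239 fell).

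**Figure D1:**
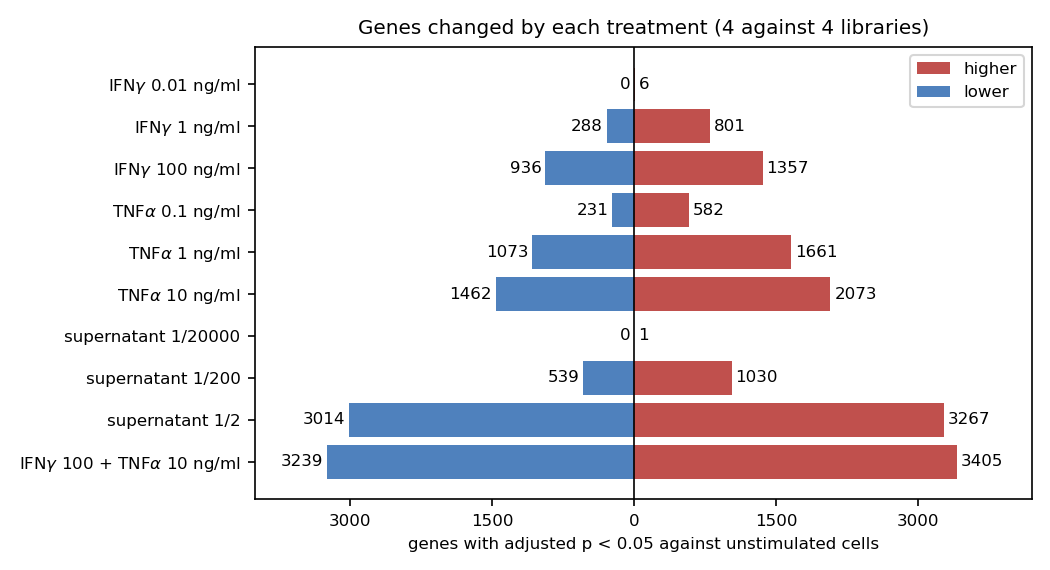
Genes higher (red, right) or lower (blue, left) than in unstimulated cells at an adjusted p below 0.05, for 10 treatments; the horizontal axis is the number of genes. Supernatant 1/2 and the combination changed more genes than either cytokine alone.

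To describe the answer to IFNγ alone, cells at 100 ng/ml were compared with unstimulated cells. IDO1, whose enzyme starts tryptophan breakdown, rose by 11.54 ± 0.31 (adjusted p = 2.3e-17; ENSG00000131203, chromosome 8 39902275 to 39928444, GRCh38). The transcription factor IRF1 rose by 4.49 ± 0.34, ETV7 by 7.76 ± 0.30 and the feedback inhibitor SOCS1 by 4.16 ± 0.36. In the JAK-STAT and interferon factor list 13 of 16 members rose, while the receptor genes IFNGR1 (-0.12 ± 0.09) and IFNGR2 (-0.23 ± 0.17) and the kinase gene JAK1 (0.03 ± 0.06) stayed near 0. All 7 guanylate-binding protein genes rose, among them GBP1 (6.20 ± 0.32), GBP4 (5.79 ± 0.38) and GBP5 (7.95 ± 0.45). So did 31 of 33 antiviral genes, such as XAF1 (4.82 ± 0.39), OAS2 (4.05 ± 0.32), MX1 (2.54 ± 0.19) and ISG15 (1.30 ± 0.12).

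Antigen presentation rose as a whole under IFNγ 100 ng/ml. All 18 members of the class I list rose, including HLA-B (1.93 ± 0.14), HLA-E (2.51 ± 0.10) and B2M (1.06 ± 0.07). They also include the peptide transporter gene TAP1 (4.29 ± 0.17; chromosome 6 32845209 to 32853978), the immunoproteasome gene PSMB9 (3.38 ± 0.14) and NLRC5 (4.69 ± 0.25), which switches on class I genes. All 13 class II members rose too, with the class II switch CIITA (5.49 ± 0.45), CD74 (4.27 ± 0.22), HLA-DRA (3.81 ± 0.25) and CTSS (3.8 ± 0.28). HLA-DQA1, without a count in unstimulated cells, rose late, to 0.171, 0.0813, 1.54 and 9.66 CPM at 2, 6, 12 and 24 h. Ligands that restrain T cells rose in parallel: 8 of 10 checkpoint genes (9 when adjusted over the list alone), with CD274, which encodes PD-L1, at 4.52 ± 0.27 and LGALS9 at 2.55 ± 0.17. PDCD1LG2, which encodes PD-L2, rose 131-fold as a ratio of pooled counts (95% counting interval 35.9 to 1090). Intervals on ratios and floors cover counting error only, and many of these ratios are carried by the late libraries.

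The T-cell attracting CXCR3 ligands all rose under IFNγ 100 ng/ml: CXCL10 by 6.63 ± 0.45, CXCL11 by 7.33 ± 0.48, and CXCL9 1060-fold (363 to 5150; 1.62, 15.4, 52.1 and 189 CPM over time). In the tryptophan list IDO1 and the tRNA synthetase gene WARS1 (3.70 ± 0.19) rose, and KYNU, further down the route, stood at -0.12 ± 0.29. Death and sensing genes rose in 17 of 25 cases, with CASP1 (4.08 ± 0.34), APOL3 (3.68 ± 0.34), FAS (2.09 ± 0.21) and MLKL (0.78 ± 0.09). Of 14 complement genes 10 rose, such as C1R (3.08 ± 0.21), C1S (3.07 ± 0.30), CFB (1.92 ± 0.14) and the inhibitor gene SERPING1 (4.77 ± 0.33). By the preset correlation the camera test called 16 of 26 lists, and 5 of them lost the call with an estimated correlation. Among these, 6 of 19 NF-κB genes rose (7 over the list alone), with adjusted p = 0.137 with an estimated correlation, and 6 of 22 chemokine and cytokine genes rose, with CSF1 at 2.43 ± 0.20 (adjusted p = 0.136 with an estimated correlation). Of 17 immediate-early genes 7 rose and 1 fell, with KLF4 at 1.33 ± 0.07 (adjusted p = 0.0889 with an estimated correlation). Of 20 hypoxia and glycolysis genes 10 rose (12 over the list alone), with EGLN3 at 1.2 ± 0.12 (adjusted p = 0.177 with an estimated correlation). Of 19 cholesterol synthesis genes 1 rose and 5 fell, with SQLE at -0.47 ± 0.09 (adjusted p = 0.382 with an estimated correlation). Cell-cycle genes kept values near 0 (MKI67 -0.02 ± 0.07, TOP2A -0.05 ± 0.08; list adjusted p = 0.441 by camera). Among the genes that fell were AXIN2 (-1.85 ± 0.29), a feedback target of Wnt signaling, SOX21 (-1.65 ± 0.28), RASSF6 (-1.64 ± 0.27) and METTL7A (-1.73 ± 0.33).

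The IFNγ 100 ng/ml count dropped to 1275 without its own 2 h library, to 1189 with no slope terms, to 252 with only the 8 libraries of the comparison and to 79 with only the 2 h and 6 h libraries. With only the 8 libraries, among others, TAP1, PSMB9, CIITA, CD74, HLA-DRA, CD274 and C1R no longer passed (adjusted p = 0.079, 0.134, 0.0949, 0.266, 0.159, 0.0795 and 0.136 by edgeR). With only 2 h and 6 h, among others, IRF1 (0.0563), HLA-DRA (0.838), CASP1 (0.172) and AXIN2 (0.359) did not pass either, all keeping their sign. Fits on these subsets of libraries also had no slope terms, so that a rise with time counted as spread.

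To describe the answer to TNFα alone, cells at 10 ng/ml were compared with unstimulated cells. CXCL8, the neutrophil attractant, rose by 6.52 ± 0.45 (adjusted p = 8.23e-10 by edgeR; chromosome 4 73740506 to 73743716), CCL2 by 6.72 ± 0.50, CCL20 by 6.08 ± 0.50 and CXCL1 by 5.65 ± 0.49. All 22 members of the chemokine and cytokine list rose, including CSF2 (6.39 ± 0.59), IL6 (4.85 ± 0.63), IL1A (4.48 ± 0.34) and TNF itself (6.78 ± 0.49). LTB rose 812-fold (224 to 6710) and CXCL5 204-fold (56 to 1690) as ratios of pooled counts. All 19 NF-κB list members rose, with the feedback genes TNFAIP3 (4.59 ± 0.35), NFKBIA (3.78 ± 0.18) and BIRC3 (3.91 ± 0.23) ahead of the subunit genes RELB (2.96 ± 0.21) and NFKB2 (2.77 ± 0.20). Of 25 cell-death genes 17 rose (18 over the list alone), such as CFLAR (1.02 ± 0.06), which blocks caspase-8; BCL2A1, which counters apoptosis, rose by 6.53 ± 0.53, and SOD2, which clears superoxide, by 3.56 ± 0.24.

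Surface and matrix genes followed. ICAM1 (4.34 ± 0.30) and VCAM1 (3.48 ± 0.40), which bind leukocytes, were among 4 of 7 adhesion genes that rose, and 8 of 10 matrix-remodeling genes rose, with MMP9 at 3.72 ± 0.54 and MMP1 at 2.08 ± 0.36. Acute-phase genes rose in 9 of 13 cases (SERPINA3 3.24 ± 0.39, SAA1 2.35 ± 0.20). TNFα 10 ng/ml also raised 17 of 18 class I genes (TAP1 1.96 ± 0.17) and 10 of 16 JAK-STAT genes, among them IFNGR2 (1.85 ± 0.16) and IFNGR1 (0.64 ± 0.09), which encode the IFNγ receptor. Class II answered in part: CTSS (2.91 ± 0.31), HLA-DRB1 (1.22 ± 0.34) and CD74 (2.15 ± 0.22) rose while HLA-DRA was at 0.41 ± 0.33 and CIITA at 1.13 ± 0.65 (list adjusted p = 0.23 with an estimated correlation). Complement genes moved both ways, 4 up and 2 down of 14, with CFB (1.85 ± 0.13) and C3 (2.96 ± 0.26) rising and CFI (-1.40 ± 0.26) falling.

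With TNFα 10 ng/ml ADH1C (-3.32 ± 0.53), METTL7A (-3.15 ± 0.38), GRAMD1B (-2.81 ± 0.37), the actin-severing gene SCIN (-2.50 ± 0.30) and the membrane estrogen-receptor gene GPER1 (-2.08 ± 0.22) were among those that fell most. Keratin genes KRT18 (-0.37 ± 0.05) and KRT8 (-0.42 ± 0.08) fell slightly, in an epithelial list with 3 up and 5 down of 14. MUC16, WT1 and ESR1 of this list, which also holds markers of ovarian carcinoma, did not pass the count filter. KLF2 fell by 1.47 ± 0.14 while JUNB rose by 2.86 ± 0.20 (10 up and 2 down of 17 immediate-early genes; adjusted p = 0.053 with an estimated correlation). In the TGF-β list 4 of 17 rose and 5 fell (SMAD6 -0.83 ± 0.14), and in the oxidative-stress list 4 of 11 rose and 2 fell. Guanylate-binding genes rose in 6 of 7 cases and checkpoint genes in 6 of 10 (7 over the list alone). Of the 17 lists called by camera 7 lost the call with an estimated correlation. Of 3 CXCR3 ligands 2 rose, with CXCL10 at 3.39 ± 0.66 (adjusted p = 0.193 with an estimated correlation). Of 33 antiviral genes 14 rose and 3 fell (15 and 4 over the list alone), with MX1 at 1.54 ± 0.20 and IFIT1 at -0.53 ± 0.15 (adjusted p = 0.216 with an estimated correlation). Of 3 tryptophan genes only KYNU rose, by 2.11 ± 0.25 (3 over the list alone; adjusted p = 0.0713 with an estimated correlation). Of 25 cell-cycle genes 5 fell, TOP2A by 0.26 ± 0.08 (adjusted p = 0.356 with an estimated correlation), and of 20 hypoxia genes 7 rose (8 over the list alone), VEGFA by 0.75 ± 0.16 (adjusted p = 0.515 with an estimated correlation). With only the 8 libraries 1382 genes passed and, among others, MMP1, CFI, ADH1C and SCIN did not (adjusted p = 0.152, 0.241, 0.199 and 0.0704 by edgeR). With only 2 h and 6 h 758 passed and, among others, MMP9 (0.468), SAA1 (0.0511), KYNU (0.241), GRAMD1B (0.149) and CXCL10 (0.067) did not. CXCL10 also failed with only 12 h and 24 h (0.0715), and CD74 with no slope terms (0.181).

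To set the cytokines against each other, IFNγ 100 ng/ml was compared directly with TNFα 10 ng/ml (4 libraries each). This gave 1611 genes higher with IFNγ and 1944 higher with TNFα. On the IFNγ side stood IDO1 (9.62 ± 0.27; adjusted p = 1.88e-16 by edgeR), the metalloreductase gene STEAP4 (7.28 ± 0.57), TRIM22 (5.61 ± 0.26), SERPING1 (4.95 ± 0.35), IRF8 (4.89 ± 0.32) and CIITA (4.36 ± 0.41). All 13 class II genes, all 7 guanylate-binding genes, 17 of 18 class I genes and 29 of 33 antiviral genes (30 over the list alone) were higher with IFNγ. On the TNFα side, TNF stood at a pooled-count ratio of 0.0042 (0.000864 to 0.0123) and LTB (-7.66 ± 0.55), CXCL8 (-7.08 ± 0.48), BCL2A1 (-6.87 ± 0.56), CSF2 (-6.67 ± 0.61) and CCL20 (-6.60 ± 0.53) were lower with IFNγ. So were 18 of 19 NF-κB genes (all 19 over the list alone) and 20 of 22 chemokine and cytokine genes; only IL15 (0.79 ± 0.18) and IL7 (0.89 ± 0.25), which sustain lymphocytes, were higher with IFNγ.

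To see how little cytokine sufficed, the lower doses were compared with unstimulated cells. At IFNγ 0.01 ng/ml 6 genes rose, among them IRF9 (1.17 ± 0.10; adjusted p = 2.13e-08 by edgeR), NLRC5 (1.71 ± 0.29), the cohesin gene REC8 (1.07 ± 0.18) and PSME2 (0.30 ± 0.06), named after their values were seen. Leaving out the IFNγ 0.01 ng/ml library of 24 h or the unstimulated library of 2 h, 6 h or 12 h gave 3, 12, 2 and 2 genes. DESeq2 gave 10, and no slope terms or only the 8 libraries gave 1 each, and edgeR on only 2 h and 6 h or only 12 h and 24 h gave 0 each. Adjusted over the list alone, 12 of 18 class I genes rose. At 1 ng/ml IFNγ already raised all 18 class I and all 13 class II genes, with IDO1 at 10.37 ± 0.32, TAP1 at 3.93 ± 0.17 and HLA-DRA at 3.34 ± 0.25. TNFα at 0.1 ng/ml raised 18 of 19 NF-κB genes (19 over the list alone) and 18 of 22 chemokine and cytokine genes (20 over the list alone). The IFNγ 1 ng/ml count was 714 or 704 without its own 6 h or 12 h library, and 709 without the unstimulated 12 h library. It was 383 with no slope terms, 254 with only the 8 libraries, 51 with only 2 h and 6 h and 613 with only 12 h and 24 h. For TNFα 0.1 ng/ml the values were 459, 435 and 419 without its 6 h, its 12 h or the unstimulated 12 h library. They were 215 with no slope terms, and 66, 238 and 4 with the 8, the earlier or the later libraries.

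To compare doses directly, IFNγ 100 ng/ml was set against 1 ng/ml and TNFα 10 against 1 ng/ml. The higher IFNγ dose raised 25 genes further, among them all 3 CXCR3 ligands (CXCL9 2.31 ± 0.18, CXCL10 1.84 ± 0.27, CXCL11 1.73 ± 0.26), IDO1 (1.16 ± 0.16), SOCS1 (1.71 ± 0.27), CD274 (1.05 ± 0.20) and SERPING1 (1.48 ± 0.23). Class I genes stood close at both doses (HLA-B 0.21 ± 0.14, TAP1 0.36 ± 0.14 between them), and 18 of 33 antiviral genes were higher only when adjusted over the list alone. Without the IFNγ 1 ng/ml library of 2 h or 24 h this count was 7 or 9, without the IFNγ 100 ng/ml library of 2, 6, 12 or 24 h it was 9, 12, 16 or 13. With no slope terms it was 2 and with DESeq2 43. Between TNFα 10 and 1 ng/ml edgeR passed 0 genes (402 before adjustment; 11 with DESeq2). With TNFα 1 ng/ml CXCL8 stood at 5.66 ± 0.46, TNFAIP3 at 4.07 ± 0.34 and NFKBIA at 3.38 ± 0.18 over unstimulated cells. The count of 2734 for this dose was 1770 without the unstimulated 2 h library, 1540 with no slope terms, and 958, 556 and 1400 with only the 8, the 2 h and 6 h or the 12 h and 24 h libraries.

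To test the cytokines together, cells given IFNγ 100 ng/ml plus TNFα 10 ng/ml were compared with unstimulated cells. CXCL10 rose by 12.80 ± 0.34 (adjusted p = 1.27e-17 by edgeR; ENSG00000169245, chromosome 4 76021117 to 76023497), CXCL11 by 12.33 ± 0.34, and CXCL9 29200-fold (9980 to 141000) as a ratio of pooled counts. UBD, which encodes the ubiquitin-like protein FAT10, rose by 12.20 ± 0.46, IDO1 by 11.97 ± 0.31, IL32 by 6.94 ± 0.17 and CTSS by 6.62 ± 0.22. ICAM1 (6.02 ± 0.32), C1S (5.77 ± 0.24) and CXCL8 (6.30 ± 0.46) rose, as did ZBP1, a sensor that triggers necroptosis, at 834-fold (149 to 33000; 51.2 CPM at 24 h and 0.0965 CPM at 2 h). ACOD1, which makes itaconate and had no count in unstimulated cells, stood at 0.0965, 1.44, 11.4 and 127 CPM over time, so that its rise rests mostly on the 24 h library; DESeq2 gave it an adjusted p of 0.406. Both programs were present in full: all 18 class I, 13 class II, 19 NF-κB and 22 chemokine and cytokine genes rose, with 32 of 33 antiviral genes and 24 of 25 cell-death genes.

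Proliferation genes fell under the combination. Of 25 cell-cycle genes 23 fell, such as TOP2A (-0.58 ± 0.08) and the replication helicase gene MCM6 (-0.73 ± 0.08; list adjusted p = 0.0438 by camera with an estimated correlation). METTL7A (-4.11 ± 0.45), GPRIN3 (-3.31 ± 0.36), AXIN2 (-2.91 ± 0.34), SGK2 (-2.91 ± 0.23) and PPARGC1A (-2.91 ± 0.31), a regulator of mitochondrial genes, were among those that fell furthest. GDF15 (-1.55 ± 0.26) and SLC7A11 (-1.10 ± 0.21) fell within an ATF4 and ER stress list with 9 up and 3 down of 18 (10 and 4 over the list alone). Hypoxia and glycolysis genes rose in 15 of 20 cases (16 up and 1 down over the list alone; NDRG1 1.77 ± 0.22, EGLN3 1.66 ± 0.12), the only list here whose call ended with an estimated correlation (adjusted p = 0.137 with an estimated correlation). With only the 8 libraries 1229 genes passed, without HLA-DRA, TOP2A, MCM6, METTL7A, SGK2 and PPARGC1A (adjusted p = 0.0629, 0.0941, 0.0512, 0.0702, 0.0941 and 0.0719 by edgeR). With only 2 h and 6 h 1661 passed, without HLA-DRA (0.277), SGK2 (0.103) and PPARGC1A (0.0648).

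To ask where the cytokines together differed from the sum of each alone, the interaction on the log2 scale was tested with the combination, IFNγ 100 ng/ml, TNFα 10 ng/ml and unstimulated cells (n = 4 each). It passed for 76 genes, 51 above the sum and 25 below it. Above it lay the laminin gene LAMA3 (1.25 ± 0.15; adjusted p = 5.29e-05 by edgeR), the cytokine receptor gene LIFR (1.05 ± 0.15), NINJ1, which ruptures the membrane of dying cells (1.69 ± 0.27), PNRC1 (1.17 ± 0.18) and the NF-κB subunit gene RELA (0.41 ± 0.09). Below it lay CSF1 (-1.86 ± 0.26), ETV7 (-3.19 ± 0.54), IRF9 (-0.56 ± 0.13) and the immunoproteasome gene PSME2 (-0.57 ± 0.08), and 12 of 18 class I genes when adjusted over the list alone. TAP1 (-1.27 ± 0.22) was also below, but not without the IFNγ 100 ng/ml library of 2 h (adjusted p = 0.0567), and C1R (1.70 ± 0.32) was above, but not without the unstimulated library of 2 h or 24 h (0.263 and 0.0739). CXCL10, for which the combination gave 5600 CPM at 12 h against 111 with IFNγ and 2.36 with TNFα, had an interaction of 2.78 ± 1.16 (adjusted p = 0.407). The count was 39 or 28 without the IFNγ 100 ng/ml library of 24 h or 2 h, 40 or 32 without the TNFα 10 ng/ml library of 24 h or 2 h. It was 41 without the unstimulated 2 h library and 116 with DESeq2. With no slope terms only 2 genes passed and every gene named here lost its call where it was recomputed (LAMA3 0.436, CSF1 0.553, TAP1 0.812, NINJ1 0.66, LIFR and PNRC1 both 0.574, C1R 0.902).

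To compare defined cytokines with what T cells and tumor cells secrete together, supernatant at 1/2 was compared with unstimulated cells. CXCL10 rose by 11.92 ± 0.34 (adjusted p = 5.89e-17 by edgeR), CXCL11 by 11.05 ± 0.35, IDO1 by 11.63 ± 0.31, UBD by 11.63 ± 0.46 and CXCL9 16500-fold (5630 to 79800). CSF3, which encodes the granulocyte growth factor G-CSF, rose at least 333-fold (6.37, 7.43, 19.2 and 54.5 CPM over time; ENSG00000108342, chromosome 17 40015361 to 40017813). IL6 (7.33 ± 0.52), CXCL1 (7.24 ± 0.46), CXCL2 (6.87 ± 0.29), CXCL8 (5.92 ± 0.46) and ICAM1 (5.75 ± 0.32) rose as they did with TNFα, and TAP1 (4.81 ± 0.18), HLA-DRA (3.61 ± 0.26) and CD274 (5.81 ± 0.27) as with IFNγ. PDCD1LG2 rose 476-fold (131 to 3940). All members rose of the class I (18), class II (13), JAK-STAT (16), guanylate-binding (7), CXCR3 (3), checkpoint (10), tryptophan (3), NF-κB (19), chemokine (22) and matrix (10) lists.

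Supernatant 1/2 also raised a stress program. Of 18 ATF4 and ER stress genes 15 rose, with the glutathione-degrading gene CHAC1 at 3.98 ± 0.49, asparagine synthetase ASNS at 1.68 ± 0.15, SESN2 at 1.66 ± 0.29, DDIT4 at 1.25 ± 0.18 and ATF4 at 0.91 ± 0.10. The list test gave adjusted p = 0.0713 with an estimated correlation. Complement genes (12 of 14; C1R 5.04 ± 0.17, CFB 4.04 ± 0.12) and acute-phase genes (10 of 13; SAA2 4.48 ± 0.29, LCN2 1.63 ± 0.10) rose. Of 25 cell-cycle genes 23 fell, with CCNE2 at -0.96 ± 0.12, RRM2 at -0.64 ± 0.07, MCM6 at -0.69 ± 0.08 and MKI67 at -0.41 ± 0.07 (list adjusted p = 0.0248 by camera with an estimated correlation). Of 19 cholesterol genes 4 rose and 9 fell, and of 20 hypoxia genes 11 rose and 1 fell (VEGFA 2.04 ± 0.15, SLC2A1 -0.73 ± 0.13; adjusted p = 0.382 with an estimated correlation). PADI1 (-3.60 ± 0.27), the xenobiotic enzyme gene CYP1A1 (-3.12 ± 0.29), METTL7A (-3.14 ± 0.39), SGK2 (-2.71 ± 0.22) and ZNF488 (-2.51 ± 0.18) were among those that fell furthest. In the marker lists of other cells few genes were measured. Of 5 T-cell genes IL2RG (3.75 ± 0.45) and CORO1A (0.63 ± 0.23) rose. Of 4 myeloid genes ITGAM (3.67 ± 0.37), CD14 (0.94 ± 0.32) and CD68 (0.44 ± 0.07) rose and LYZ fell by 1.07 ± 0.35. COL1A1, the only measured fibroblast gene, stood at 0.25 ± 0.26. Of 13 mitochondrially encoded genes MT-ND1 (-0.16 ± 0.06) and MT-ND2 (-0.14 ± 0.05) fell, though neither passed when adjusted over the list alone. With only the 8 libraries 1188 genes passed, without ASNS, SESN2, MKI67, MCM6, LCN2, PADI1, METTL7A, SGK2, ZNF488 and HLA-DRA (adjusted p = 0.0841, 0.155, 0.0726, 0.069, 0.0575, 0.103, 0.119, 0.143, 0.0912 and 0.0922 by edgeR). With only 2 h and 6 h 1450 passed, without MKI67 (0.0546), MCM6 (0.106), PADI1 (0.133), METTL7A (0.119), SGK2 (0.167), ZNF488 (0.0934) and HLA-DRA (0.544).

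Diluted supernatant was compared in the same way. At 1/200 the IFNγ-type genes still rose (IDO1 9.86 ± 0.34, CXCL10 6.29 ± 0.44, TAP1 4.02 ± 0.17, HLA-DRA 2.95 ± 0.27; all 18 class I and 13 class II genes), and 12 of 19 NF-κB genes rose (15 over the list alone), with BIRC3 at 1.88 ± 0.22 and NFKBIA at 1.13 ± 0.18. At 1/20000 the only gene past the test was IRF9 (0.78 ± 0.10; adjusted p = 0.00025 by edgeR), named after its value was seen. The 1/200 count was 915 or 945 without its 12 h or 2 h library, 996 or 951 without the unstimulated 2 h or 12 h library, and 520 with no slope terms. It was 413 with only the 8 libraries and 47 with only 2 h and 6 h. At 1/20000 the count was 2 or 3 without its 12 h or 24 h library, 2 without the unstimulated 2 h library, 2 with only the 8 libraries and 6 with DESeq2. With edgeR the call ended (0 genes) with no slope terms, with only 2 h and 6 h and with only 12 h and 24 h.

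To find where the supernatant differed from IFNγ and TNFα at these doses, supernatant 1/2 was compared directly with the combination (n = 4 each). The IFNγ and TNFα content of the supernatant is not given in the sources used here, so that differences may also come from dose. The comparison passed for 1223 genes, 652 higher and 571 lower in supernatant. CSF3 was 3.62 ± 0.40 higher (adjusted p = 1.09e-05 by edgeR) and CISH, a target of STAT5, 1.85 ± 0.26 higher. By duration the CSF3 difference was 3.32, 4.86, 4.07 and 1.33 at 2, 6, 12 and 24 h, smallest at 24 h. Its ratio of pooled counts was 3.78. GDF15 was 1.98 ± 0.26 higher, but the combination had lowered it against unstimulated cells. Of 18 ATF4 and ER stress genes 11 were higher and 1 lower (13 and 1 over the list alone). These included ASNS (1.48 ± 0.15; adjusted p = 1.3e-06; ENSG00000070669, chromosome 7 97852118 to 97872542), the serine synthesis genes PHGDH (1.27 ± 0.15) and PSAT1 (1.17 ± 0.18) and ATF4 (0.65 ± 0.10), with ATF5 lower (-0.41 ± 0.11). CHAC1 (2.16 ± 0.43) and SESN2 (1.25 ± 0.29) were higher too, but CHAC1 not without the supernatant library of 24 h or 2 h (adjusted p = 0.146 and 0.464) and SESN2 not without these (0.284 and 0.454) or the combination library of 2 h (0.0725). The ASNS difference was 0.89, 1.18, 1.03 and 2.6 at 2, 6, 12 and 24 h, largest at 24 h.

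**Figure D2:**
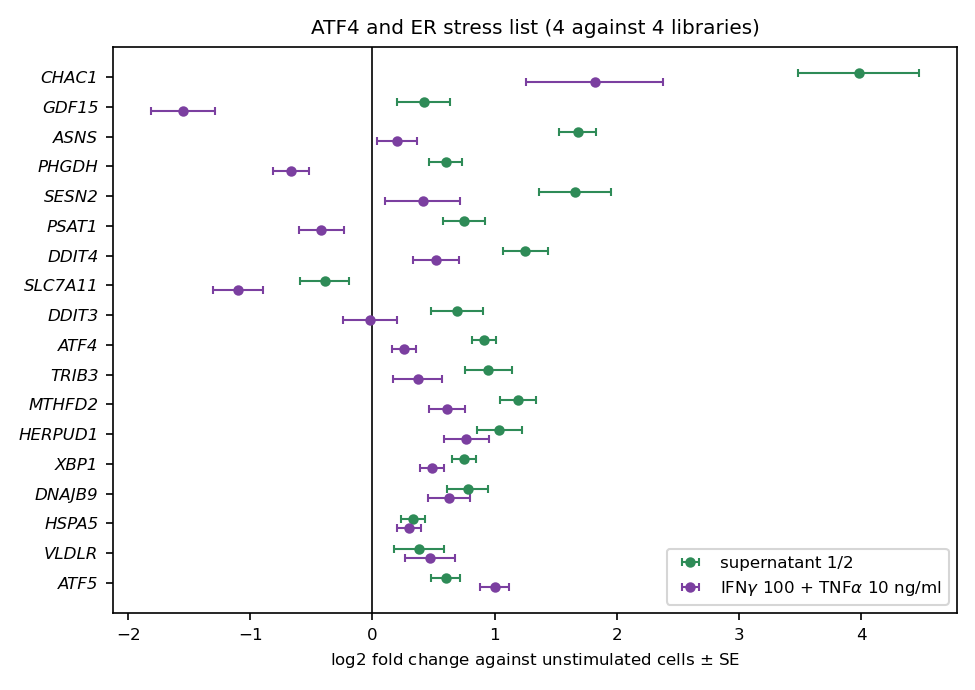
Log2 fold change against unstimulated cells ± SE for 18 members of the ATF4 and ER stress list, with supernatant 1/2 in green and the combination in purple (4 libraries against 4). Of the 18 genes 11 were higher and 1 lower with supernatant than with the combination. The list medians were near level at 12 h (0.55 and 0.53) and furthest apart at 24 h (1.55 and 0.66).

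Of 13 acute-phase genes 4 were higher with supernatant 1/2 and 1 lower (8 and 1 over the list alone), with LCN2 at 1.27 ± 0.09 and SERPINA3 at 1.22 ± 0.30. The protease gene MMP7 (1.10 ± 0.18), IL6 (1.15 ± 0.30), NFKBIZ (0.88 ± 0.13) and VEGFA (1.09 ± 0.14) were higher as well. Lower with supernatant than with the combination were the CXCR3 ligands CXCL9 (-1.06 ± 0.10), CXCL10 (-0.88 ± 0.17) and CXCL11 (-1.28 ± 0.16), CCL2 (-1.51 ± 0.28) and ZBED2 (-2.18 ± 0.37). Also lower were 14 of 33 antiviral genes (21 over the list alone), such as RSAD2 (-1.28 ± 0.18) and MX1 (-1.08 ± 0.16), 9 of 20 hypoxia genes (14 over the list alone; PDK1 -0.57 ± 0.13) and 6 of 19 cholesterol genes (8 over the list alone; HMGCS1 -0.66 ± 0.09). IDO1 (-0.34 ± 0.16) and CD274 (-0.01 ± 0.18) were near equal. The count was 667 without the combination library of 2 h and 442 with no slope terms, where CCL2 (adjusted p = 0.0572 by edgeR) and CXCL11 (0.0669) no longer passed.

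To follow the answer over time, the change of each treatment effect per doubling of the exposure was estimated as a slope. With IFNγ 100 ng/ml 364 genes had a rising and 132 a falling slope. Class II genes built up late: HLA-DRA gained 2.32 ± 0.23 per doubling (adjusted p = 1.98e-07 by edgeR), HLA-DRB1 2.12 ± 0.27 and CD74 2.08 ± 0.18, and 7 of 13 class II genes passed (11 over the list alone), as did 16 of 18 class I genes. HLA-DRA stood at 1.2, 7.07, 45.6 and 173 CPM at 2, 6, 12 and 24 h, and IDO1 at 2.48, 674, 2580 and 6710 CPM. The log2 ratio of IDO1 to unstimulated cells was 3.95, 11.94, 10.6 and 11.17, so that its treatment effect did not grow after 6 h. Unstimulated cells had only 48 IDO1 counts in all. IRF1 was already at 926 CPM at 2 h and stayed there (1020, 996 and 1060 CPM; unstimulated 58.6 at 2 h). With TNFα 10 ng/ml 212 slopes rose and 176 fell. MMP9 gained 2.18 ± 0.51 and the phospholipase gene PLA2G4C 1.24 ± 0.20 per doubling. The NF-κB genes BCL3 (-0.74 ± 0.12), REL (-0.37 ± 0.09) and MAP3K8 (-0.45 ± 0.12) lost ground. CXCL8 dropped from 978 CPM at 2 h to 262 CPM at 6 h and stayed near it. Its log2 ratio to unstimulated cells was 7.06, 5.73, 6.47 and 6.58 at 2, 6, 12 and 24 h, so that its treatment effect largely held. Supernatant 1/2 gave 1207 rising and 1144 falling slopes. HLA-DRA rose by 2.48 ± 0.23 and CD74 by 2.14 ± 0.18 per doubling, and 16 of 25 cell-cycle genes (22 over the list alone) and 7 of 19 cholesterol genes (HMGCS1 -0.55 ± 0.07) fell with time.

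**Figure D3:**
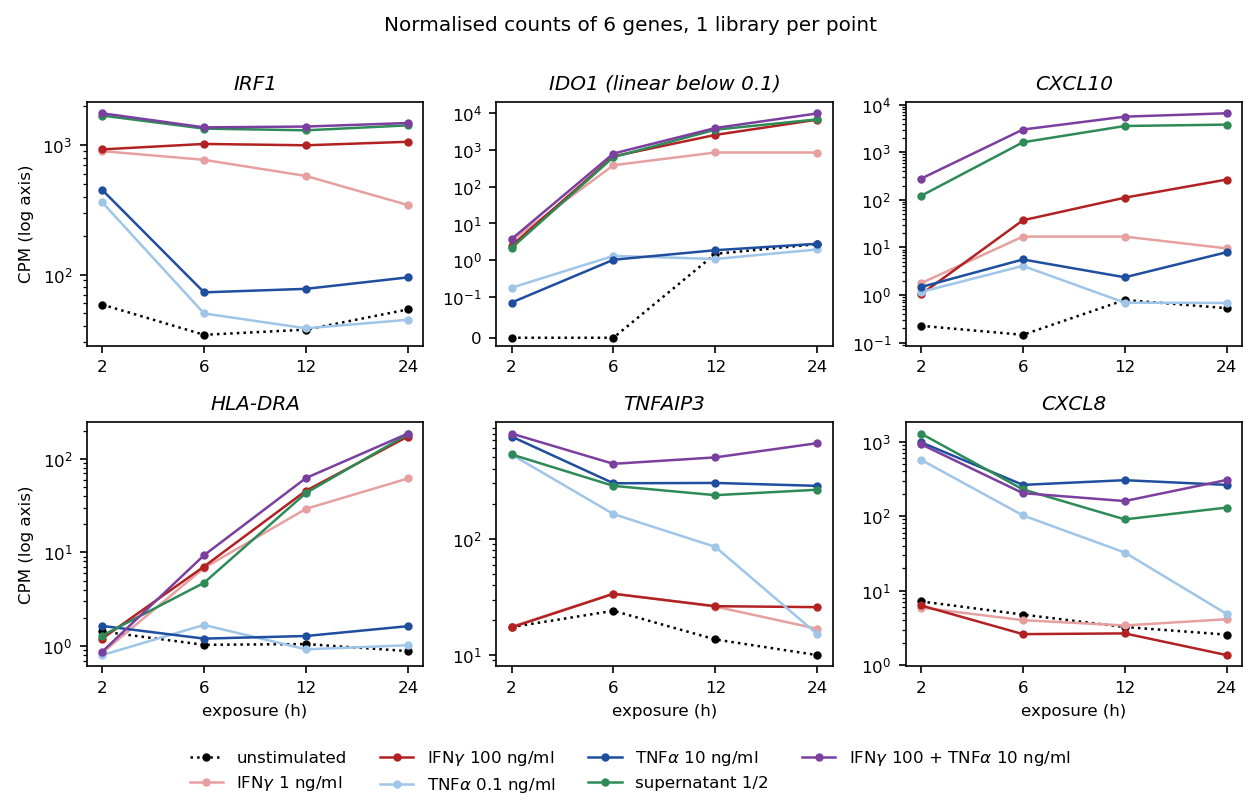
CPM on a log axis against hours of exposure for IRF1, IDO1, CXCL10, HLA-DRA, TNFAIP3 and CXCL8 under 7 treatments, with 1 library per point. IRF1, TNFAIP3 and CXCL8 were high by 2 h, whereas the CPM of IDO1 and HLA-DRA climbed later. With IFNγ 100 ng/ml the log2 ratio of IDO1 to unstimulated cells was 11.94 at 6 h and 11.17 at 24 h. CXCL10 climbed mostly between 2 h and 6 h with IFNγ 100 ng/ml (log2 ratios 1.59, 6.88, 6.85 and 8.57 at 2, 6, 12 and 24 h). With supernatant 1/2 and the combination its log2 ratio was already 8.26 and 9.45 at 2 h, and 12.31 and 13.2 at 6 h.

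Slope counts rested on few libraries. For IFNγ 100 ng/ml the count of 496 was 171 or 169 without its 24 h or 2 h library and 43 without the unstimulated 2 h library. For TNFα 10 ng/ml the count of 388 was 16 or 79 without its 24 h or 2 h library and 1, 247 or 235 without the unstimulated library of 2, 12 or 24 h. MMP9 lost its call without the TNFα library of 24 h (adjusted p = 0.183 by edgeR) or the unstimulated library of 2 h (0.289) or 24 h (0.133), and PLA2G4C without the unstimulated 2 h library (0.54). For supernatant 1/2 the count of 2351 was 460 or 1510 without the unstimulated library of 2 h or 24 h. The 2 h and 6 h libraries carry sample numbers apart from the 12 h and 24 h libraries, which leaves a difference between sequencing pools possible. A pool difference shared by all treatments is taken up by the factor for duration. Only a pool difference that is unlike between treatments could enter the slopes.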

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

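The 4 tests of technical explanations in these paragraphs were chosen after the results they weigh were seen, and the splits of libraries were chosen before.

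Of 18 ATF4 and ER stress genes 11 were higher and 1 lower with supernatant 1/2 than with the combination, for example ASNS (1.48 ± 0.15; adjusted p = 1.3e-06 by edgeR, n = 4 each). The excess was uneven over time. Over unstimulated cells the list median was 0.39, 0.62, 0.55 and 1.55 at 2, 6, 12 and 24 h with supernatant 1/2. With the combination it was 0.06, 0.18, 0.53 and 0.66, so that the medians were near level at 12 h and furthest apart at 24 h. RNA of T cells carried over with the supernatant is argued against: the 8 T-cell transcripts of the test had 1 count over the 4 supernatant 1/2 libraries (0.0205 CPM), against a gain of 42.1 CPM for ASNS. For ER stress, HSPA5, DNAJB9, HERPUD1 and XBP1 had a median difference of 0.2 (range 0.03 to 0.27). The other 14 members had 0.72, and 11 of them were higher. These values argue against ER stress that raises the 4 genes as much as the others. ER stress that acts mainly through ATF4 cannot be judged from the 4 genes and stays open. Nutrient loss in conditioned medium or a further secreted factor could produce the pattern with 0.2 for the ER genes; neither was tested here.

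Class II genes rose with time under IFNγ 100 ng/ml, and duration coincides with possible sequencing pools, inferred from sample numbers alone. Within the 12 h and 24 h libraries alone the median change of the class II log2 ratios was 1.83 (13 of 13 rose), and within 2 h and 6 h alone it was 3.02 (12 of 13 rose). A difference between the pools is unlikely to be the cause, since it would leave no change within the libraries of a pool (1.83 and 3.02).

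The chemokine and cytokine genes CCL2, CXCL2, TNF and LTB had lower slopes over time under TNFα 0.1 ng/ml than under 10 ng/ml. Between the doses the median log2 difference of the chemokine and cytokine list changed by -1.39 from 12 h to 24 h (21 of 22 fell) and by -0.46 from 2 h to 6 h (20 of 22 fell). As both steps lie within an inferred pool, a pool difference is unlikely to be the cause.

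Genes whose treatment effect differed between groups numbered 76 for the interaction of the cytokines, 496, 388 and 2351 for the slopes of IFNγ 100 ng/ml, TNFα 10 ng/ml and supernatant 1/2, 31 for TNFα 0.1 against 10 ng/ml slopes and 10 for IFNγ 1 against 100 ng/ml slopes.

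Single durations stood apart from the other 3 by Dixon's test on log2 ratios in 9 of 128 groups, where about 1 in 20 would do so by chance. With IFNγ 100 ng/ml these were the 2 h values of IDO1 (3.95), CIITA (1.58), PDCD1LG2 (0.09) and APOL3 (0.55), with TNFα 10 ng/ml the 2 h value of NFKBIA (4.72), with supernatant 1/2 the 2 h values of CXCL10 (8.26) and IDO1 (3.76) and the 12 h value of CYP1A1 (-3.72), and with the combination the 2 h value of IDO1 (4.52). None of the 33 groups of library totals or shares did so. The libraries of a group are different durations, so that an early value that stands apart is also what a delayed answer gives.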

How the results depend on the processing

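RLE scaling moved no count by more than 1.5 times (22 compared), and scaling shifted the share of genes called higher by at most 3.9 points. No filter moved only the TNFα slope difference, to 20. No slope terms left 6 counts near and moved IFNγ 0.01, 1 and 100 ng/ml to 1, 383 and 1189, TNFα 0.1 and 1 ng/ml to 215 and 1540. It moved supernatant 1/200 and 1/20000 to 520 and 0, IFNγ 100 against 1 ng/ml to 2, the interaction to 2, supernatant against the combination to 442 and supernatant 1/200 against IFNγ 1 ng/ml to 0. DESeq2 left 13 near and moved, in the same terms, IFNγ 0.01 ng/ml to 10, supernatant 1/20000 to 6, IFNγ 100 against 1 to 43, TNFα 10 against 1 to 11, the interaction to 116, the TNFα and IFNγ slope differences to 74 and 24, and supernatant 1/200 against IFNγ 1 to 14. For IFNγ 0.01, 1, 100, TNFα 0.1, 1, 10, supernatant 1/2, 1/200, 1/20000 and the combination, only the 8 libraries gave 1, 254, 252, 66, 958, 1382, 1188, 413, 2 and 1229. Only 2 h and 6 h gave 0, 51, 79, 238, 556, 758, 1450, 47, 0 and 1661. Only 12 h and 24 h moved IFNγ 0.01 and 1 to 0 and 613, TNFα 0.1 and 1 to 4 and 1400, and supernatant 1/20000 to 0. The fits on the 8 libraries and on pairs of durations had no slope terms, so fewer libraries are not their only change. Leaving out 1 library moved 57 of 196 counts; without the library named, the values were as follows. IFNγ 0.01, own 24 h 3, unstimulated 2, 6, 12 h 12, 2, 2. IFNγ 1, own 6, 12 h 714, 704, unstimulated 12 h 709. IFNγ 100, own 2 h 1275. TNFα 0.1, own 6, 12 h 459, 435, unstimulated 12 h 419. TNFα 1, unstimulated 2 h 1770. Supernatant 1/200, own 12, 2 h 915, 945, unstimulated 2, 12 h 996, 951. Supernatant 1/20000, own 12, 24 h 2, 3, unstimulated 2 h 2. For IFNγ 100 against 1, IFNγ 1 at 2, 24 h 7, 9, IFNγ 100 at 2, 6, 12, 24 h 9, 12, 16, 13. Interaction, IFNγ 2, 24 h 28, 39, TNFα 2, 24 h 32, 40, unstimulated 2 h 41. Supernatant against the combination, combination 2 h 667. Slopes of IFNγ 100, own 24, 2 h 171, 169, unstimulated 2 h 43. TNFα 10, own 24, 2 h 16, 79, unstimulated 2, 12, 24 h 1, 247, 235. Supernatant 1/2, unstimulated 2, 24 h 460, 1510. TNFα slope difference, 0.1 at 2, 12, 24 h 187, 63, 1, 10 at 2, 6, 24 h 14, 12, 1. IFNγ slope difference, 1 at 2, 6, 24 h 28, 2, 0, 100 at 24 h 1. Supernatant 1/200 against IFNγ 1, IFNγ at 2, 6, 12, 24 h 1, 2, 1, 1, supernatant at 2, 12 h 0, 1. The lowest and highest were 2 and 12 (IFNγ 0.01), 704 and 1119 (1), 1275 and 2001 (100), 419 and 944 (TNFα 0.1), 1770 and 2525 (1), 2357 and 3219 (10). They were 4993 and 6029 (supernatant 1/2), 915 and 1424 (1/200), 1 and 3 (1/20000), 5087 and 6315 (combination). They were 2553 and 3109 (IFNγ against TNFα), 7 and 32 (IFNγ 100 against 1), 28 and 106 (interaction), 667 and 1364 (supernatant against the combination), 43 and 528, 1 and 360, 460 and 2590 (slopes), 1 and 187, 0 and 28 (slope differences), and 0 and 3 (supernatant 1/200 against IFNγ 1). List calls ranged from 68 to 71. Of 104 list tests 70 passed with the preset correlation and 55 with an estimated correlation. Named genes kept their call in 2618 cases and lost it in 218, of which 112 by leaving out 1 library. This tally covers only genes named in the text, and among those left out a change of direction did occur. The cause of these changes was not tested.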

Other observations

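The comparisons of slopes between doses and of supernatant 1/200 with IFNγ 1 ng/ml, and the genes named in these paragraphs, were chosen after the values were seen; all tests are by edgeR with Benjamini-Hochberg adjustment.

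For some genes the effect grew less, or fell, with time at a low dose when compared with a high dose. At 2 h TNFα 0.1, 1 and 10 ng/ml gave CXCL8 at 570, 879 and 978 CPM (unstimulated 7.15 CPM); at 24 h the values were 4.85, 44.8 and 262 CPM (unstimulated 2.56 CPM), although CXCL8 did not pass the test of unlike slopes. Slopes differed between 0.1 and 10 ng/ml for 31 genes, and for 28 of them the slope was lower at the lower dose. The differences of slopes, 0.1 less 10 ng/ml, included CCL2 (-1.53 ± 0.25 per doubling; adjusted p = 0.0114 by edgeR), TNF (-1.20 ± 0.22), LTB (-1.25 ± 0.25), CXCL2 (-0.97 ± 0.17), SOD2 (-0.88 ± 0.17) and the pathway inhibitor NFKBIA (-0.72 ± 0.12). For IFNγ the slopes of 10 genes differed, all lower at 1 than at 100 ng/ml, with differences such as CXCL9 (-1.39 ± 0.16; adjusted p = 8.31e-05 by edgeR), CXCL10 (-1.64 ± 0.25), CXCL11 (-1.74 ± 0.25) and LGALS9 (-0.59 ± 0.11). IRF1 began level, at 898 and 926 CPM at 2 h with 1 and 100 ng/ml, and ended at 344 and 1060 CPM at 24 h. The TNFα count was 63, 1 or 187 without the 0.1 ng/ml library of 12, 24 or 2 h, 12, 1 or 14 without the 10 ng/ml library of 6, 24 or 2 h. It was 20 with no filter and 74 with DESeq2. The IFNγ count was 2 or 28 without the 1 ng/ml library of 6 h or 2 h, 0 without that of 24 h (edgeR), 1 without the 100 ng/ml library of 24 h and 24 with DESeq2. Decay of the cytokine or its uptake by the cells may lower the dose over time, which would also give the change of -1.39 from 12 h to 24 h in the chemokine list; this was not tested.

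Supernatant 1/200 was compared directly with IFNγ 1 ng/ml (n = 4 each). In this comparison 4 genes differed, all higher with supernatant: IL32 (1.18 ± 0.15; adjusted p = 0.00129 by edgeR), NFKBIE (0.73 ± 0.12; 0.00813), IRAK2 (0.70 ± 0.12; 0.0211) and CXCL10 (1.5 ± 0.25; 0.0211). Of 19 NF-κB genes 1 was higher with supernatant (5 over the list alone). CXCL10 stood at 5.84, 46.1, 45.8 and 31.9 CPM with supernatant 1/200 and at 1.77, 16.9, 16.9 and 9.56 CPM with IFNγ 1 ng/ml at 2, 6, 12 and 24 h. The count was 1, 2, 1 or 1 without the IFNγ 1 ng/ml library of 2, 6, 12 or 24 h, and 1 without the supernatant library of 12 h. It was 0 with edgeR without the supernatant library of 2 h or with no slope terms, and 14 with DESeq2.

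A few genes known from lymphocytes, picked after their values were seen, rose in these cultures. CD69, a marker of T-cell activation, rose 102-fold (27.9 to 850, counting error only) with TNFα 10 ng/ml and reached 4.09 ± 1.79 CPM (mean ± SD over 4 durations, n = 4) against 0.0402 ± 0.0468 CPM unstimulated. IL2RG, the common chain of interleukin receptors, rose with TNFα 10 ng/ml (2.45 ± 0.48) and stood at 1.12, 1.52, 6.34 and 25 CPM over time with supernatant 1/2 and at 0.772, 1.17, 4.69 and 17 CPM with the combination. In the fixed list of T-cell markers 1 of 5 measured genes rose with TNFα 10 ng/ml.

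Of the 35 splits of the libraries into groups of the same sizes, only the real split reached the following counts (1 of 35). These were IFNγ 1 ng/ml 1089 (highest other 747), IFNγ 100 ng/ml 2293 (1849) and TNFα 0.1, 1 and 10 ng/ml 813, 2734 and 3535 (650, 1259 and 2025). They were also supernatant 1/2 and 1/200 6281 and 1569 (5188 and 1003), the combination 6644 (5827), IFNγ against TNFα 3555 (2447), supernatant against the combination 1223 (1095), supernatant 1/200 against IFNγ 1 ng/ml 4 (2) and the TNFα 10 ng/ml list tests 17 (16). The groups are matched by duration, however, and only 8 of the 35 splits keep 1 library of each duration in each group. That is too few for a share under 0.05, and the remaining splits mix treatment with duration. Chance is therefore not excluded for the counts above. Nor can it be excluded for IFNγ 0.01 ng/ml (6, highest other 9, 2 of 35 splits as large), supernatant 1/20000 (1, 23, 8 of 35) or IFNγ 100 against 1 ng/ml (25, 27, 2 of 35). The same holds for the list tests of IFNγ 100 ng/ml (16, 16, 2 of 35), supernatant 1/2 (19, 20, 8 of 35) and the combination (18, 19, 7 of 35). Among the 8 matched splits only the real split was as large for IFNγ 0.01 ng/ml (highest other 1) and IFNγ 100 against 1 ng/ml (22). This was also so for the list tests of IFNγ 100 ng/ml (15) and the combination (17). For supernatant 1/20000 and the supernatant 1/2 list tests 3 of 8 were as large. Between TNFα 10 and 1 ng/ml edgeR called 0 genes (402 before adjustment; 11 with DESeq2), so that all 35 splits are as large by construction (highest other 5) and nothing is tested.

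Nor can chance be excluded in this way for the interaction (76; 3646; 8 of 60) or the slopes of IFNγ 100 ng/ml (496; 951; 5 of 35), TNFα 10 ng/ml (388; 2015; 5 of 35) and supernatant 1/2 (2351; 4527; 7 of 35), nor for the slope differences of TNFα (31; 772; 8 of 35) and IFNγ (10; 151; 6 of 35). For slopes the highest other split joined the treated 12 h and 24 h libraries with the unstimulated 2 h and 6 h libraries, which turns a treatment effect into a slope, and for the interaction it mixed the IFNγ 12 h library with unstimulated ones.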
